A study of Danio rerio with 12 samples.

How the data were processed

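Total RNA from adult zebrafish kidneys was sequenced in 12 samples, 3 from wild-type fish and 9 from fish heterozygous for a pdx1 mutation. Per the labels' protocols, kidneys were kept in RNAlater, RNA was isolated with the RNeasy kit on a QIAcube, and libraries followed the standard BGISeq-500 protocol. The labels gave no sex, age, family, batch or pooling, and did not say whether each sample was 1 fish, so the p-values measure the spread between these samples.

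The deposited files held 2 kinds of values per sample. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.4 and quantified with kallisto, listed as version 0.4.6, on genome build GRCz11. The annotation, the kallisto settings and the step from transcripts to genes were not given in the sources used here. The deposited estimated counts were not normalized and were given for 30238 Entrez gene IDs, and between 50.6% and 51.9% of the values in a sample were not whole numbers. The deposited TPM values (scaled by the authors for transcript length and library size) were used in alternatives and in a check of effective length. Gene symbols came from a RefSeq gene table of another assembly, GRCz12tu, which named 25812 of the 30238 IDs and left 4426 without a symbol. That table was used for names, biotypes and the order of neighbouring genes, and none of its coordinates are given. Because kallisto divides reads that fit several transcripts, levels of genes with near-identical copies are uncertain. Whether counting used the strand was not given in the sources used here.

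Estimated counts were rounded to whole numbers and analysed in R 4.3.3. Genes passing filterByExpr of edgeR 4.0.16 (minimum count 10) were kept, which left 23732. Libraries were scaled by TMM, and groups were compared with the edgeR quasi-likelihood F test with robust estimation, all 12 samples in 1 fit and no covariate. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Standard errors of log2 fold changes are approximate, taken as the fold change divided by the square root of F. CPM values used the TMM-scaled library sizes, and log2 CPM for scores used a prior count of 2. Of the genes outside the filter, only pdx1 and ins were compared. They were tested by an exact two-sided permutation test of CPM over all 220 splits of the samples into 3 and 9.

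A total of 51 gene lists (cell types, pathways and organelles) were fixed before the data were examined. The 49 lists with at least 5 tested members were compared with the other genes by camera in limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 49. Each list was also tested with an estimated correlation, with fry, and by an exact permutation test of its score, the mean centred log2 CPM of its members per sample. A list's members were adjusted over the list alone as well as over all genes tested.

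Genes named in the text followed a rule fixed in advance. It took pdx1 and ins, then up to 10 genes per direction past the threshold. These needed a mean CPM of at least 2, a symbol that is not a clone or accession style name, and 1 direction in at least 8 of the 9 heterozygous samples. If none passed, the 10 such genes with the smallest p were taken. The rule also took up to 4 members with the smallest p of each list described. Statements on other genes were chosen after their values were seen. The single-gene result of 1 gene that the rule names is not reported here, and it is left out of the counts of named genes.

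Alternatives were other scalings, filters and thresholds, DESeq2 1.42.0, limma-voom with and without sample quality weights, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), and surrogate variables from sva 3.50.0. Replicate numbers as a block, and each sample left out in turn, were also tried. The fits with 2 and 3 surrogate variables, with the ribosomal RNA level as a covariate, and the permutation test of list scores were chosen after the data were seen.

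The edgeR step was tested on simulated data drawn for the 23732 genes of this comparison. It called 42.0% of the 100 genes changed 2-fold and 89.9% of the 99 genes changed 4-fold. Among its 137 calls, 6 genes had not been changed. With no change simulated it called 0 genes, and camera called 0 lists. Simulated genes varied independently, so the simulation does not cover genes that vary together between fish.

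A floor of 3 counts corresponded to between 0.156 and 0.184 CPM. Floors and intervals of shares cover counting error only. No pair of samples agreed within sampling noise: the lowest chi-square per gene between any pair of libraries was 17.3.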

Results

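Kidneys of adult zebrafish were profiled by RNA sequencing in 3 wild-type samples and 9 samples from fish heterozygous for a mutation in pdx1 (pdx1+/-), a homeobox gene required for pancreas development and beta cell function. In fish the kidney holds both nephrons and the main blood-forming tissue, so its RNA comes from tubule, vessel and blood cells together. Totals were 1.76e+07 ± 381350 estimated counts in the wild-type samples (SD, n = 3) and 1.77e+07 ± 924615 in the heterozygous samples (SD, n = 9). The design implies 1 comparison, of the kidney transcriptome between the 2 genotypes.

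The mutated gene itself was at the edge of detection. The estimated counts of pdx1 (Entrez 30721) were 14, 10 and 6 in wild-type replicates 1 to 3. Among the 9 heterozygous samples, 5 had a count of 0 and the others had 8, 7, 10 and 2. Mean levels were 0.570 ± 0.247 CPM (SD, n = 3) and 0.166 ± 0.225 CPM (SD, n = 9), a log2 ratio of -1.78 (exact two-sided permutation test over 220 splits, p = 0.0273). The p was 0.109 in the exact test without wild-type replicate 1 and 0.0727 without wild-type replicate 2. Transcripts of ins (Entrez 30262), the insulin gene of the pancreatic beta cell, summed to 4 counts in the wild-type and 8 in the heterozygous samples, and no difference was detectable at this depth (exact permutation p = 1).

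**Figure D1:**
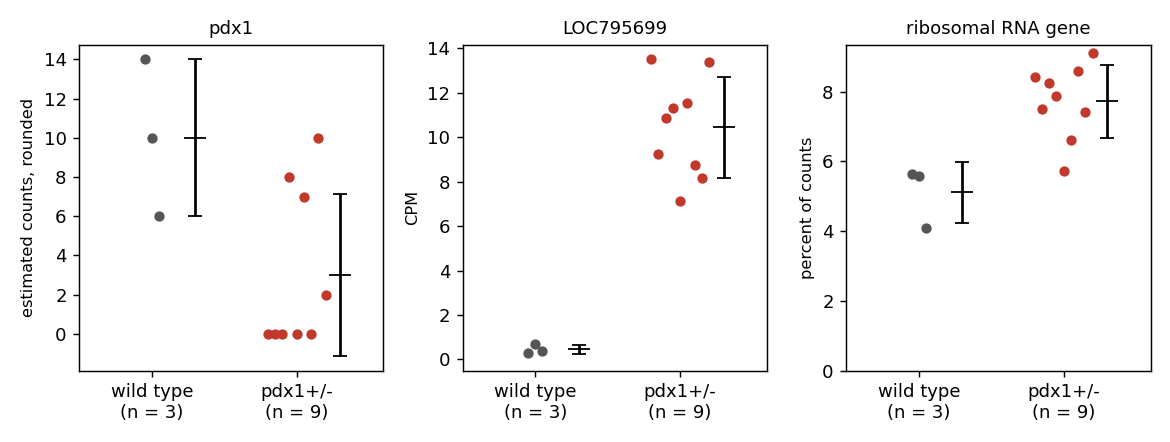
Estimated counts of pdx1, CPM of LOC795699 and the percent of counts from the ribosomal RNA gene, for wild-type (grey) and pdx1+/- (red) samples. Each point is 1 sample and the black marks give the mean and SD; LOC795699 reached at most 0.681 CPM in wild type and at least 7.11 CPM in pdx1+/-.

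Of 23732 genes tested, 1 passed the threshold. LOC795699, listed as a pseudogene, was higher in 9 of 9 heterozygous samples, at 10.4 ± 2.25 CPM (SD, n = 9) against 0.450 ± 0.204 CPM (SD, n = 3). Its log2 fold change was 4.51 ± 0.32 (approximate SE; edgeR quasi-likelihood test, adjusted p = 5.53e-05). Its clone-style name falls outside the naming rule, so it was named after its value was seen. Its estimated counts were not whole numbers in any of the 12 libraries, within a tolerance of 0.001, so part of its reads may also fit other transcripts. In the 9 heterozygous libraries the same held for 9159 of the 23732 tested genes. At an unadjusted p under 0.05, 1347 genes were found where 1187 are expected with no change. Over 100 splits of the 12 samples into 3 and 9, this share was 5.68% in the real split and from 1.33% to 17.2% in the others. The count therefore does not set the genotypes apart. DESeq2 called 61 genes, 43 higher and 18 lower in heterozygous kidneys.

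None of the 10 named genes with the smallest p passed the threshold in edgeR, while DESeq2 called all 10 on the same samples (adjusted p from 1.16e-06 to 0.00591). Each lay on 1 side of the wild-type mean in 9 of 9 heterozygous samples. The naming rule itself required at least 8 of 9, so this agreement was nearly set by the selection. Lowest in p was krt18b, a keratin of simple epithelia, with 314 ± 26.0 CPM in wild type (SD, n = 3) and 168 ± 24.6 CPM in heterozygous kidneys (SD, n = 9). Its log2 fold change was -0.91 ± 0.12 (edgeR, adjusted p = 0.0639). It became a call in edgeR without heterozygous replicate 2 (adjusted p = 0.0246) and without heterozygous replicate 5 (adjusted p = 0.0288). Single genes were followed in 4 alternatives (RLE scaling, DESeq2, limma-voom and the replicate block) and in the 12 fits without 1 sample. Over these, the adjusted p of krt18b ranged from 1.16e-06 (DESeq2) to 0.586. Without heterozygous replicate 5, cd9r and csf1rb also became calls in edgeR (adjusted p = 0.0477 and 0.0220). For tagln3b, a transgelin family gene, the log2 fold change was -1.36 ± 0.20 (edgeR, adjusted p = 0.0803). That of cd9r, a tetraspanin gene, was 1.14 ± 0.18 (edgeR, adjusted p = 0.105). The log2 fold changes of csf1rb, a macrophage growth factor receptor, selp, which encodes P-selectin, and sdsl, a serine dehydratase-like gene, were -0.96, -0.58 and -0.61. Those of ftr11, a fish-specific TRIM gene, the chemokine gene ccl34b.8, ifi44c2 and uba7, the ISG15-activating enzyme, were 3.39, 2.57, 1.36 and 0.90. The edgeR adjusted p of these 7 genes lay between 0.242 and 0.342.

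Genes next to pdx1 held more small p-values than genes elsewhere, a comparison chosen after the gene table was seen. Among the 100 tested genes nearest to pdx1 in the gene order of the RefSeq table, 24 had an unadjusted edgeR p under 0.05, against 5.68 expected (one-sided Fisher exact p = 1.26e-09, which treats genes as independent). Of the 24, 18 were lower and 6 higher in heterozygous kidneys. LOC795699, with 46 tested genes between it and pdx1, and tagln3b, with 6 between, were both among them. The excess went on past these 100 genes, with 36 of the nearest 200 (11.4 expected) and 57 of the nearest 400 (22.7 expected). Of the named genes, ccl34b.8 was the 109th tested gene on 1 side of pdx1. On the 24 other chromosomes, no run of 100 tested genes held more than 15. With the 100 neighbours left out, no gene passed the threshold in edgeR (lowest adjusted p = 0.127). This outcome was close to given, since LOC795699, the only gene called, was left out with them. Of the 61 genes called by DESeq2, 7 were among the 100, against 0.257 expected.

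**Figure D2:**
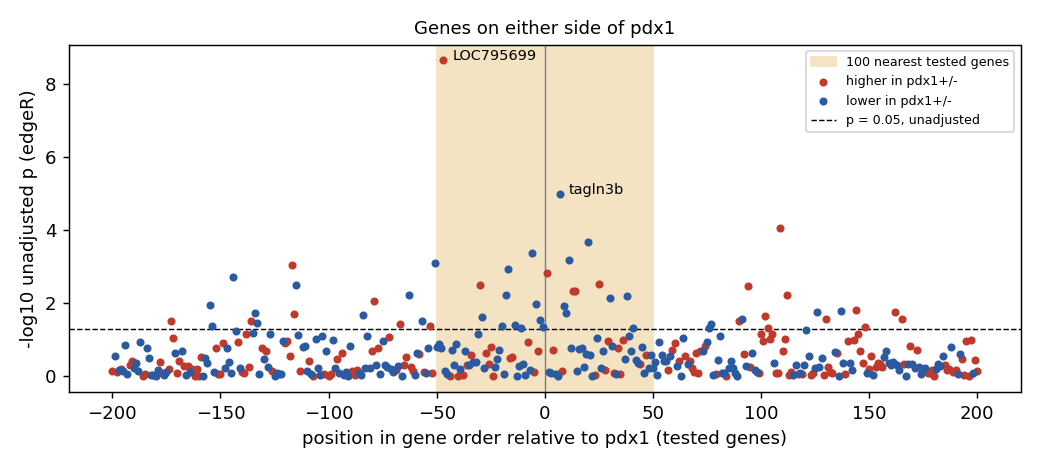
Unadjusted edgeR p (as -log10) of tested genes by their position in gene order on either side of pdx1, red where higher and blue where lower in pdx1+/- kidneys. In the shaded run of 100 genes, 24 points lie above the dashed line at an unadjusted p of 0.05.

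Of the 49 gene lists tested, camera called 13, with 5 higher and 8 lower in heterozygous kidneys. None of their members passed the threshold over all genes tested in edgeR. In DESeq2 5 did: ifi27.2 (adjusted p = 0.000110) and mxa (0.0323) of interferon response, cd4-1 (0.0390) and ccl36.1 (0.0426) of T and NK cell, and selp (0.00130) of thrombocyte. No list passed with an estimated correlation between genes, which for the 13 ranged from 0.0248 to 0.728, above the preset 0.01. None passed fry's test of a shared direction either (lowest adjusted p = 0.120). In fry's test for changes in either direction 2 lists passed, interferon response (adjusted p = 0.0183) and macrophage and dendritic cell (adjusted p = 0.0392).

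Interferon response genes showed the clearest shift. Of 64 tested members, 58 had higher and 6 lower levels in heterozygous kidneys, with a median log2 fold change of 0.55 (camera, adjusted p = 6.23e-30; adjusted p = 0.129 with an estimated correlation). Adjusted over the list alone, 24 members passed in edgeR, all of them higher. For ifi27.2, an interferon-inducible gene, levels were 38.9 ± 18.7 CPM (SD, n = 9) against 6.78 ± 2.98 CPM (SD, n = 3), a log2 fold change of 2.52 ± 0.57. The antiviral GTPase gene mxa had a log2 fold change of 1.11 ± 0.27, ifi44g of 0.52 ± 0.13 and the guanylate-binding protein gene gbp2 of 0.79 ± 0.23. Over all genes, the edgeR adjusted p of these 4 lay between 0.514 and 0.694. The list score was higher than in every wild-type sample in 9 of 9 heterozygous samples (exact permutation p = 0.00455, the smallest possible with 220 splits; adjusted over 49 lists, p = 0.223). None of the list's members were among the 100 tested genes nearest to pdx1.

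**Figure D3:**
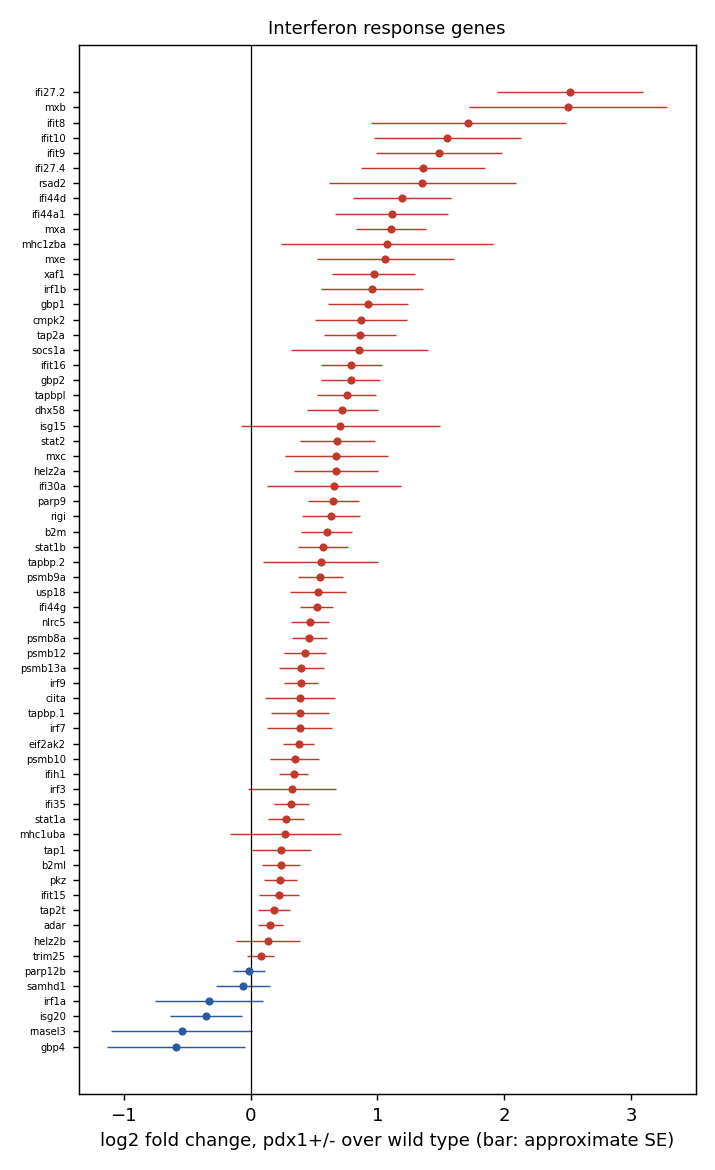
Log2 fold change of each of the 64 tested interferon response genes, pdx1+/- over wild type, with its approximate SE. Higher genes are red (58) and lower ones blue (6).

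T and NK cell genes were higher as a list, with 43 of 51 tested members higher and a median log2 fold change of 0.45 (camera, adjusted p = 1.10e-09; adjusted p = 0.483 with an estimated correlation). Adjusted over the list alone, 2 members passed in edgeR: the T helper cell coreceptor gene cd4-1, with a log2 fold change of 1.35 ± 0.33, and the chemokine gene ccl36.1, with 0.83 ± 0.20. Values for nitr5, an immune-type receptor gene, and ccl38a.5 were 1.74 ± 0.55 and 1.77 ± 0.61. The score exceeded every wild-type sample in 6 of 9 heterozygous samples (exact permutation test, unadjusted p = 0.0773).

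The share of counts from the annotated ribosomal RNA gene moved with these groups. It was 5.11% ± 0.874 in wild type (SD, n = 3) and 7.72% ± 1.05 in heterozygous libraries (SD, n = 9), and the groups did not overlap (exact permutation p = 0.00455; adjusted over 4 library measures, p = 0.0182). With the log2 level of this gene as a covariate, a fit chosen after the data were seen, 13 lists were called by camera, of which 6 were among the original 13. The interferon list remained among them. The T and NK cell list did not (camera, adjusted p = 0.0952), and neither did the endothelium, insulin, basement membrane, thrombocyte, multiciliated cell and hypoxia lists.

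Energy and protein turnover genes were also higher as lists. Of 92 nuclear-encoded genes of mitochondrial oxidative phosphorylation, 70 were higher, with a median log2 fold change of 0.12 (camera, adjusted p = 0.00139; adjusted p = 0.865 with an estimated correlation). Examples were ndufa13, a complex I subunit, at 0.37 ± 0.11, and atp5mc3a, an ATP synthase subunit, at 0.35 ± 0.11. Of 42 proteasome genes, 30 were higher, with a median of 0.15 (camera, adjusted p = 0.00508; adjusted p = 0.865 with an estimated correlation). Among them psmc5 had a log2 fold change of 0.40 ± 0.16 and psmb3 of 0.37 ± 0.16. Multiciliated cell genes were higher in 36 of 50, with a median of 0.16 (camera, adjusted p = 0.0198; adjusted p = 0.865 with an estimated correlation). The ciliogenesis regulator genes gmnc and rfx3 had log2 fold changes of 1.17 ± 0.42 and 0.42 ± 0.16. Adjusted over the list alone, 0 members of these 3 lists passed in edgeR. With the replicate numbers as a block the oxidative phosphorylation and proteasome lists were in the opposite direction (camera, adjusted p = 0.967 and 0.475). In that fit only the samples numbered 1 to 3 inform the group difference. Among them genotype is partly confounded with another split of the samples, described below with their spread. Without wild-type replicate 1 all 3 calls ended (camera, adjusted p = 0.582, 0.338 and 0.922 in the same order). The multiciliated call also ended without wild-type replicate 3 (camera, adjusted p = 0.159) and without heterozygous replicate 1 (camera, adjusted p = 0.0524).

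Vessel and platelet genes were lower as lists. Of 58 genes of endothelium and angiogenesis, 43 were lower, with a median log2 fold change of -0.15 (camera, adjusted p = 0.000586; adjusted p = 0.483 with an estimated correlation). The endothelial cadherin gene cdh5 had 142 ± 13.9 CPM (SD, n = 9) against 183 ± 23.0 CPM (SD, n = 3), a log2 fold change of -0.36 ± 0.11. Values for the scavenger receptor genes lyve1b and mrc1a and the VEGF receptor gene kdrl were -0.54, -0.50 and -0.28. Of 40 basement membrane genes, 27 were lower, with a median of -0.11 (camera, adjusted p = 0.0113; adjusted p = 0.483 with an estimated correlation). Among them were hspg2, which encodes perlecan, at -0.31 ± 0.11 and the collagen IV gene col4a2 at -0.31 ± 0.12. Thrombocytes are the nucleated platelets of fish, and 22 of 28 of their genes were lower, with a median of -0.09 (camera, adjusted p = 0.0182; adjusted p = 0.483 with an estimated correlation). Adjusted over the list alone, selp passed in edgeR, with 40.3 ± 4.71 CPM against 60.1 ± 2.52 CPM, while 0 genes of the endothelial and basement membrane lists did. The basement membrane call ended without wild-type replicate 1 (camera, adjusted p = 0.162). The thrombocyte call ended without wild-type replicate 1 (camera, adjusted p = 0.0783) and without wild-type replicate 3 (camera, adjusted p = 0.517).

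Signalling and clock lists were lower by small amounts. Of 62 insulin and IGF signalling genes, 46 were lower, with a median log2 fold change of -0.14 (camera, adjusted p = 0.00459; adjusted p = 0.460 with an estimated correlation). The PI3-kinase subunit genes pik3r3a and pik3ca had values of -0.44 ± 0.16 and -0.20 ± 0.08, akt1 of -0.22 ± 0.09, and the insulin receptor gene insrb of -0.31 ± 0.14. Of 48 circadian clock genes, 31 were lower, with a median of -0.13 (camera, adjusted p = 0.00937; adjusted p = 0.483 with an estimated correlation). The period gene per1a had -0.51 ± 0.16 and the cryptochrome gene cry1b -0.49 ± 0.16. Of 50 hypoxia response genes, 34 were lower, with a median of -0.10 (camera, adjusted p = 0.0269; adjusted p = 0.483 with an estimated correlation), among them epas1b at -0.62 ± 0.22. In edgeR 0 members of these 3 lists passed adjusted over the list alone. Without wild-type replicate 1 all 3 calls ended (camera, adjusted p = 0.147, 0.368 and 0.0676). The hypoxia call also ended without wild-type replicate 3 (camera, adjusted p = 0.185).

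Proximal tubule genes were lower in 38 of 60, with a median log2 fold change of -0.08 (camera, adjusted p = 0.0113; adjusted p = 0.780 with an estimated correlation). The phosphate transporter gene slc34a1a had 37.9 ± 10.6 CPM (SD, n = 9) against 73.8 ± 17.6 CPM (SD, n = 3), a log2 fold change of -0.96 ± 0.24. The organic anion transporter gene slc22a6l, the sodium-hydrogen exchanger gene slc9a3.1 and the multidrug exporter gene slc47a2.1 had values of -0.92, -0.48 and -0.38. With 1 sample left out in turn, these ranged from -1.12 to -0.41, from -0.65 to -0.15 and from -0.50 to -0.25. Mitochondrially encoded mRNAs were lower in 8 of 10, with a median of -0.21 (camera, adjusted p = 0.0166; adjusted p = 0.865 with an estimated correlation). For the complex I genes ND4 and ND4L the log2 fold changes were -0.36 ± 0.12 and -0.32 ± 0.13. In edgeR 0 members of these 2 lists passed adjusted over the list alone. Both calls ended without wild-type replicate 2 (camera, adjusted p = 0.175 and 0.750) and without heterozygous replicate 2 (camera, adjusted p = 0.0949 and 0.0841). The mitochondrial call also ended without heterozygous replicate 5 (camera, adjusted p = 0.0744).

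Some of these lists, at least thrombocyte, multiciliated cell, T and NK cell and endothelium, also differed in part along ddc, a gene of aromatic amino acid metabolism whose levels lay in 2 separate ranges within both genotypes, a link seen after the data were examined. Wild-type replicate 2 and heterozygous replicates 1, 3, 4, 6 and 9 had at least 4332 CPM of ddc, and the other 6 samples at most 220 CPM. The thrombocyte score was -0.24 in wild-type replicate 2 and -0.32 to -0.17 in those 5 heterozygous samples. It was 0.25 and 0.40 in wild-type replicates 1 and 3 and 0.16 to 0.26 in heterozygous replicates 2, 5, 7 and 8. The multiciliated cell score was highest of all 12 samples in wild-type replicate 2, at 0.23. It was -0.38 and -0.17 in wild-type replicates 1 and 3, and -0.24, -0.19, 0.01 and 0.10 in heterozygous replicates 5, 8, 7 and 2. In heterozygous replicates 1, 3, 4, 6 and 9 it was 0.10 to 0.18. Of the 6 heterozygous samples with a T and NK cell score above every wild-type sample, 5 were replicates 1, 3, 4, 6 and 9, while the highest score, 0.63, was in replicate 2. The endothelium score was between -0.22 and -0.09 in wild-type replicate 2 and heterozygous replicates 3, 4, 6 and 9. It was 0.19 in heterozygous replicate 1 and from 0.00 to 0.18 in the 6 samples with little ddc. The first surrogate variable was negative in the 6 samples with much ddc and positive in the 6 with little, so the fit that includes it adjusts for this split. In that fit the thrombocyte and multiciliated cell lists did not pass (camera, adjusted p = 0.0750 and 0.132), while the interferon, T and NK cell and endothelium lists did (camera, adjusted p = 1.77e-30, 4.91e-09 and 0.000600).

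**Figure D4:**
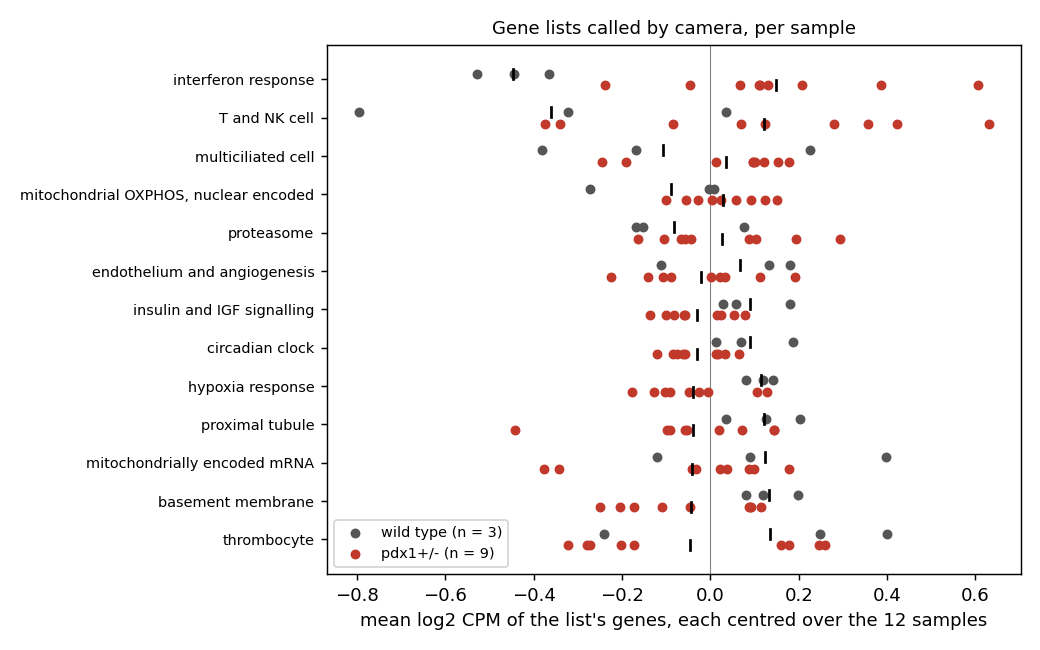
Score of each of the 13 called gene lists (mean log2 CPM of its genes, each centred over the 12 samples) for wild-type (grey) and pdx1+/- (red) samples. Each point is 1 sample and black ticks mark group means; for interferon response all 9 pdx1+/- points lie to the right of the 3 wild-type points.

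The 36 other tested lists did not pass in camera, with adjusted p between 0.0540 and 0.982. Markers of neighbouring organs were among them, namely endocrine pancreas, exocrine pancreas, hepatocyte, intestine, skeletal muscle, testis, and interrenal and chromaffin cells. Other kidney and blood cell lists that did not pass were distal tubule and collecting duct, podocyte, erythroid, neutrophil, macrophage and dendritic cell, B cell, haematopoietic stem and progenitor cell, and immunoglobulin segments. Metabolic lists that did not pass were gluconeogenesis, glycolysis, polyol and related sugar pathways, carbonyl detoxification, fatty acid oxidation and ketones, sterol and fatty acid synthesis, purine and uric acid metabolism, amino acid catabolism, steroid and xenobiotic metabolism, and solute carriers. The same held for oxidative stress, inflammatory cytokines, fibrillar matrix, kidney injury, immediate early genes, heat shock, endoplasmic reticulum stress, cell cycle, p53 and apoptosis, ribosomal proteins, and vacuolar ATPase and lysosome. Corpuscle of Stannius and ovary had 4 tested members each, too few for the test. Single members passed in edgeR adjusted over the list alone: krt18b of kidney injury, sdsl of amino acid catabolism, csf1rb of the progenitor list and igldcp of the immunoglobulin list. In the macrophage and dendritic cell list 4 passed, with csf1rb and spi1b lower and ccl34b.8 and ctss2.1 higher. These members of lists that did not pass were chosen after their values were seen.

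Samples of the 2 genotypes were about equally far from each other within their groups. The mean distance between samples over the 500 most variable genes was 77.0 in wild type and 74.8 in heterozygous kidneys, on the log2 CPM scale (exact two-sided permutation test, p = 0.632). This compares spread alone and does not address other groupings of the samples. On the same genes the first principal component held 22.2% of the variance and split both genotypes. Wild-type replicate 3 and heterozygous replicates 1 to 3 had scores of 31.7 to 35.7, and the other samples -8.60 or lower. The second, with 19.8%, was positive in the samples with much ddc and negative in those with little. What underlies the first split was not tested.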

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

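The tests of the ribosomal RNA share, of T and NK cells and of the effective length of klf2a were chosen after their results had been seen, while the other tests were set before their own results, though after the patterns they address. The test of genes near pdx1 was chosen after the gene table was seen, and its comparison with other splits, like the share of all tested genes highest in heterozygous replicate 2, after its result. For the ribosomal RNA share and for T and NK cells, the requirement that the difference left over exclude 0 was added after the first outcome, which without it counted against the ribosomal RNA share. Among 83 values or genes examined in the 9 heterozygous samples, 7 had 1 sample far from the others by Dixon's test. Chance alone gives such a value in about 1 of 20 groups.

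Heterozygous replicate 5 stood out in csf1rb, with 138 CPM against 76.8 to 101 CPM in the other 8. Heterozygous replicate 1 had the most col4a2, 188 CPM against 122 to 143 CPM. Heterozygous replicate 2 had the most mxa, 27.4 CPM against 10.4 to 16.5 CPM, the most ctss2.1, a cathepsin S gene, 116 CPM against 52.5 to 75.8 CPM, and the lowest proximal tubule score, -0.44 against -0.10 to 0.15. The ins level of heterozygous replicate 3 was 0.244 CPM, which is 4 counts, against at most 0.114 CPM.

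In heterozygous replicate 2, klf2a, a transcription factor gene, took 9.98% of all counts (± 0.0140 as an exact 95% interval), against 0.121% to 0.213% in the other heterozygous libraries. Its level was 73.8 times the median of the other 11 libraries. The effective length of klf2a in this library differed by 0.207% from the median of the others, within their own range of -0.336% to 0.606%. This cannot decide on reads from another transcript, since a gene with 1 annotated transcript keeps its effective length whatever its reads. The number of annotated klf2a transcripts was not known. An admixture of other material stays open: 4 genes, klf2a itself and ptgs2a, aoc1 and cplx1, lay over 10 times above every other library, too few to decide, against 34 in heterozygous replicate 4. Other immediate early genes may have been raised in the same kidney, since 61.3% of 62 were highest in this library against 15.5% of all tested genes (one-sided binomial p = 3.26e-16, genes taken as independent; p = 1.25e-25 against the 1 in 12 set beforehand, too low a baseline). Their median was 1.86 times the median of the other libraries, far below the change in klf2a.

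LOC795699, the 1 gene called, may differ because of sequence variants carried along with the pdx1 mutation, a hypothesis found and tested on the same data. Of the 100 tested genes nearest to pdx1, 24 had an unadjusted p under 0.05, and 23 without LOC795699. Over 100 splits of the 12 samples into 3 and 9, the real one included, the highest other count was 21, and relative to all genes the real ratio of 4.23 was the highest, with 4.05 next. Reads shared with a similar gene also stay open, since the estimated count was whole in 0 of 9 heterozygous libraries, as for 9159 of 23732 tested genes, and no similar copy was identified. A general difference between families stays open: 1 gene was under 1 CPM throughout 1 group and over 3 CPM throughout the other, but it was LOC795699 itself, so this count decides nothing (up to 4 genes in other splits of the 220).

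The camera p of the higher interferon response list was not matched by the same list in another split drawn. Of 100 splits, 1, the real one, gave a camera p as small (1.27e-31). The lowest p of the others, 7.33e-27, came from a split with 2 of the 3 wild-type samples in the group of 3. The list was picked for its p in the real split and was not compared with the lowest list of each other split. Its top rank is therefore in part set by that choice. Adjusted over all lists tested, the exact permutation p of its score was 0.223, the lowest that a lone list can reach. Setting heterozygous replicates 2, 4 and 6 against the rest gave a camera p of 3.15e-22. The rest held all 3 wild-type samples, which had the lowest scores, so this split cannot show variation apart from genotype. Within the heterozygous samples alone the score ranged from -0.239 in replicate 5 to 0.606 in replicate 2. More T and NK cells alone would account for 0.13 of the score difference of 0.59 (value 0.127, 95% interval -0.07 to 0.33), judged from the slope within groups, and 0.47 was left over (0.10 to 0.84). The ribosomal RNA share, as a sign of RNA quality or library preparation, would account for 0.13 (value 0.133, 95% interval -0.31 to 0.57). What was left, 0.46 (-0.09 to 1.02), could be 0, so this explanation cannot be told apart from an effect of the genotype, which stays open and untested.

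The counts of calls themselves do not exclude chance. Of the 100 splits, 19 called at least 1 gene, the number in the real split, and the highest of the others was 25. As many as the real 13 lists were called in 70 splits, with up to 22 in the others, so a structure of the samples other than genotype also produces list calls.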

How the results depend on the processing

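The fits with 2 or 3 surrogate variables and with the ribosomal RNA covariate, and the permutation test of list scores, were chosen after the data were seen. The count of 1 called gene became 61 in DESeq2, 3 in limma-voom with quality weights, 3 in limma-trend on log2(TPM + 0.1) and 2 with 2 surrogate variables. It was 5 in the 6 samples numbered 1 to 3 without a block. Leaving out 1 sample gave 1 to 4 genes, with 4 without heterozygous replicate 5 and 2 without heterozygous replicate 2. LOC795699 was among the calls in each of these. The replicate numbers did not pair the samples: deviations of same-numbered samples correlated at -0.216, -0.159 and 0.0964, and no wild-type sample correlated best with its own number. With the replicate block the count was 0 in all 12 samples and 0 in the 6, and 12 lists were called, 5 of them among the original 13. The higher replicate numbers occur in the heterozygous group alone, so under the block only the 6 samples numbered 1 to 3 inform the group difference. The 2 counts of 0 thus rest on nearly the same comparison. Of these 6 samples, wild-type replicates 1 and 2 were low on the first principal component. Wild-type replicate 3 and heterozygous replicates 1 to 3 were high. Genotype is therefore partly confounded with that component in the block fits and in the fit of the 6 samples without a block. LOC795699 kept a log2 fold change of 4.62 in the block fit of all 12 samples (edgeR, adjusted p = 0.569). With the block the oxidative phosphorylation and proteasome lists were in the opposite direction (camera, adjusted p = 0.967 and 0.475). With the ribosomal RNA covariate the multiciliated and thrombocyte lists were in the opposite direction (camera, adjusted p = 0.433 and 0.906). The 13 list calls became 0 with an estimated correlation, 0 with fry's test of a shared direction and 0 by the permutation test of scores. That last count says little, since with 220 splits a lone list has an adjusted p of at best 0.223 over 49 lists. Unadjusted, 3 of the 49 lists had an exact p under 0.05. Leaving out 1 sample gave 6 to 19 lists, 6 without wild-type replicate 1 and 19 without wild-type replicate 2. The interferon, T and NK cell and endothelium lists stayed called in all 12 such fits. The log2 ratio of pdx1 lay between -2.06 and -1.43 without 1 wild-type sample, and passed the permutation test only without replicate 3 (p = 0.0182). The cause of these changes was not tested, except that fewer samples inform the group difference in block fits and where some are left out. The other settings changed neither count by over 1.5 times. The fold changes of 64 named genes kept their direction in all 1024 comparisons run. That set was narrowed to the genes of called lists and those past a threshold after a wider set, with members of each list, had shown reversals. Of 3237 values for 203 genes, 35 in 19 genes were in the opposite direction, 0 of them past the threshold. Among the 19 were stc1, zar1, nobox and stc1l, and with the replicate block prss59.1 went from 5.25 to -0.14 and tfa from 4.08 to -0.75. The samples with the most of these 2 transcripts, heterozygous replicates 8 and 4, do not inform the group difference in that fit. The median log2 fold change of all genes was at most 0.03 under 4 scalings. Depth limits pdx1 and ins, which lie near the floor of 3 counts.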

Other observations

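The DESeq2 alternative, set before the data were examined, called 61 genes, which the edgeR test did not except for LOC795699. All 61 had an unadjusted edgeR p under 0.05. Of these 61, 2 (ifi27.2 and mxa) belonged to the interferon list where 0.165 is expected (one-sided Fisher exact p = 0.0119). This test treats genes as independent, while the estimated correlation between genes of the list was 0.210. The list was also picked on the same samples, so this p adds no separate evidence for it. Of the 61, 7 were among the 100 genes nearest to pdx1 where 0.257 is expected. The genes named next were chosen after their values were seen. Higher in DESeq2 were socs1b, a suppressor of cytokine signalling, with a log2 fold change of 1.76 ± 0.40 (adjusted p = 0.0119), and the complement gene c4, with 1.23 ± 0.31 (adjusted p = 0.0403). Lower were apoeb, an apolipoprotein E gene, with -1.50 ± 0.37 (adjusted p = 0.0328), the mannose receptor gene mrc1b, with -0.59 ± 0.15 (adjusted p = 0.0364), and actb2, a cytoplasmic actin gene, with -0.40 ± 0.10 (adjusted p = 0.0245).

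Some kidneys held RNA typical of neighbouring organs. In heterozygous replicate 4, 34 genes of at least 5 CPM lay over 10 times above every other library, and 12 of them were on the hepatocyte list of 20 tested members. Its level of apoa1b, an apolipoprotein gene, was 878 CPM against at most 23.3 CPM elsewhere, and that of the transferrin gene tfa was 495 CPM against at most 12.2 CPM. The trypsin gene prss59.1 was at 23.5 CPM in heterozygous replicate 8 and 8.91 CPM in heterozygous replicate 4, and at most 0.724 CPM in the other 10 samples.

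The level of ddc, which encodes aromatic amino acid decarboxylase, fell into 2 separate ranges within both genotypes. It was 135, 6391 and 197 CPM in wild-type replicates 1 to 3. In heterozygous replicates 1 to 9 it was 4851, 220, 6469, 4332, 111, 4988, 138, 121 and 5620 CPM. The bile acid enzyme gene cyp7a1 was at 0.234, 524 and 0.378 CPM in the same wild-type samples. It was between 201 and 254 CPM in heterozygous replicates 1, 3, 4, 6 and 9 and at most 0.374 CPM in the others. The labels give no sex or age, and the samples were not tested as groups by these values, though the first surrogate variable has opposite signs in the 2 ranges.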
